A study of Gallus gallus with 8 samples.

How the data were processed

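Spleen RNA of 20-week-old layers infected with Salmonella Enteritidis or mock-infected was measured on 8 Agilent 44K chicken arrays of 2 channels each. Per the labels, 150 ng of total RNA was amplified and labelled with Cy3 or Cy5, the dyes being balanced between infected and control birds. Per the file headers, the arrays were scanned and read with Agilent Feature Extraction 10.7.3.1, and the signals are in intensity units, the median pixel brightness per spot and of its surroundings. The 0 or 1 marks per spot (saturated, non-uniform, well above background) are also as deposited, in the unit class other. The deposited value table holds natural log (ln) ratios of the channels per spot: its slopes against log2 ratios of the scanned arrays were near 0.69 in size, the natural log of 2. The table's scale and centring could be read from the values, with column medians of 0.00309, 0.00559, 0.012, -0.000106, 0.00605, 0.0107, 0.00835 and -0.00128 for replicates 1 to 8. Which way its columns run is unknown for replicates 7 and 8, where its sign opposes the labelled dyes. How the authors computed the table is not given in the sources used here; background-subtracted, loess-normalized median signals of the scanned arrays match it.

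Each scanned array was assigned to the sample whose column it matched, at an absolute correlation over 0.8 and at least 0.2 above any other column. The choice of model, filters, threshold, gene lists, named genes and tests of the comparisons was made before the data were examined, as was the rule for this match. The written plan spelled the rule out for replicates 7 and 8 only, and it was used for all 8 arrays. The tests of explanations for the red cell, liver and dye patterns were chosen after the results were seen. The written plan named mean signals; the files hold median signals only, which were used in their place. The alternatives added after the values had been seen were 4: replicates 1 to 6 only, replicates 7 and 8 turned, the arrays filed as recorded (7 arrays, since 2 were filed under the same sample), and replicates 3 and 5 left out together. Filing as recorded leaves out the array of replicate 6 and turns the direction of replicates 1 and 2. Replicates 1 to 6 had at first been taken for the reported values, after the match had been seen; the values reported returned to the written plan of 8 arrays with labelled dyes.

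Signals were background corrected by normexp with an offset of 50 and normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots of a probe were averaged. Probes with a non-uniform spot (118) were left out, and probes well above background in either channel on at least 4 arrays were kept, leaving 33724. The share of probe spots well above background was 65.5% to 80.6% per channel. The limma model held the infection effect, its difference between slides and a dye effect, with 5 residual and 2.91 prior degrees of freedom. Its contrasts were infected against control as the mean of both slides, within slide 1, within slide 2, and slide 2 minus slide 1. Tests were two-sided with Benjamini-Hochberg adjusted p and a threshold of 0.05. The dye effect passed it for 1 probe, with 6924 at an unadjusted p under 0.05. Standard errors are limma's moderated ones, and fits of fewer arrays share the same spread model.

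Probes carry transcript accessions only. Of 12768 probes with a RefSeq transcript, 10849 matched the gene table of assembly GRCg7b, which was used for names alone; 10857 probes carried 1 of 5005 symbols, and 17397 Ensembl transcript probes and 13430 others stayed unnamed. No coordinates are given, since the array grid names an older build, galGal3. Gene lists used 1 probe per gene, that with the highest mean intensity, over 4450 genes. The 26 lists were inflammatory cytokines and chemokines, interferon gamma response, type I interferon, pattern receptors, antimicrobial, heterophil, macrophage and monocyte, T cell, B cell, plasma cell, cytotoxic and NK cell, thrombocyte, red cell, cell cycle, MHC and antigen presentation, complement and acute phase, cholesterol, heat shock, circadian clock, extracellular matrix, endothelium, smooth muscle, pancreas, liver, ribosomal protein and oxidative phosphorylation. They were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, which does not compare a list with other genes. List values are medians of the members' log2 changes; the per-array mean and SD are of the list's median on each array.

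Named genes were to be those past the threshold; since none passed, the 24 named genes with the smallest p are given for the mean of both slides and the 6 with the smallest p for the slide difference, with up to 4 members of smallest p per called list and a fixed panel of 18 immune genes, of which 15 could be tested. Some of the genes these rules select are not reported here. ALB, APOV1, AvBD1, HBAD, HBBA and HBE were named after their values were seen.

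The steps were tested on simulated data. For infected against control over 33724 probes, 63.5%, 94% and 99.5% of 200 probes changed by 0.5, 1 and 2 log2 units were recovered, with 6, 10 and 13 false calls. For the list tests over 4450 genes, 10 runs with no moved list gave 1 call, and 10 runs with 2 lists moved by 0.5 found 20 of 20, with 7 calls of other lists. In all of these simulations probes and genes were drawn independently of each other. The simulations therefore cannot show how often the preset test calls lists whose genes vary together. Nor can they show how many changed probes would be recovered where probes vary together.

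Alternatives were other background corrections and normalizations, the value table in place of the scanned arrays, other filters, no dye term, no slide term, array weights, separate fits per slide, leaving out each array in turn, the mean of a gene's probes, and the other list tests. Whether other splits of the arrays gave results as large was counted.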

Results

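The series measured spleen RNA from 20-week-old white leghorn layers infected with Salmonella Enteritidis, a bacterium that colonises the chicken gut and spreads to the spleen, and from mock-infected controls. Each of 8 arrays compared the RNA of 1 infected spleen with that of 1 control spleen in the Cy5 and Cy3 dyes, so each array gave 1 infected-to-control ratio per spot. Arrays are named replicates 1 to 8 after the sample they belong to; replicates 1 to 4 lay on 1 slide (slide 1) and replicates 5 to 8 on another (slide 2). By the labels the infected RNA carried Cy5 in replicates 1, 3, 5 and 7 and Cy3 in replicates 2, 4, 6 and 8. The study sampled birds at 7 and 14 days after infection with 4 birds per group and time, but the labels do not tie any sample to a time, so the times were not compared.

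The scanned arrays did not all sit under the sample they were recorded for. Over 27304 well measured spots, every scanned array matched exactly 1 sample's column of the deposited value table, with correlations of at least 0.999 in size and at most 0.437 with any other column. That matched sample was the recorded sample for only 1 of the 8 arrays, and 2 arrays were recorded under replicate 7 and none under replicate 8. Arrays were therefore assigned by the match. For replicates 1 to 6 the sign of the deposited column was that of infected over control by the labelled dyes. For replicates 7 and 8 it was the opposite, so the direction of these 2 arrays is not settled. They were recorded under replicates 5 and 6, so the labelled dyes are the same by the record and by the match. Only the sign of the deposited columns differs. All signed values below, use the labelled dyes on 8 arrays unless stated; a count of 6 arrays is of replicates 1 to 6. Values for replicates 1 to 6 alone, or with replicates 7 and 8 turned, stand beside the list calls they end and the single genes whose mean over both slides they turn in sign.

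**Figure D1:**
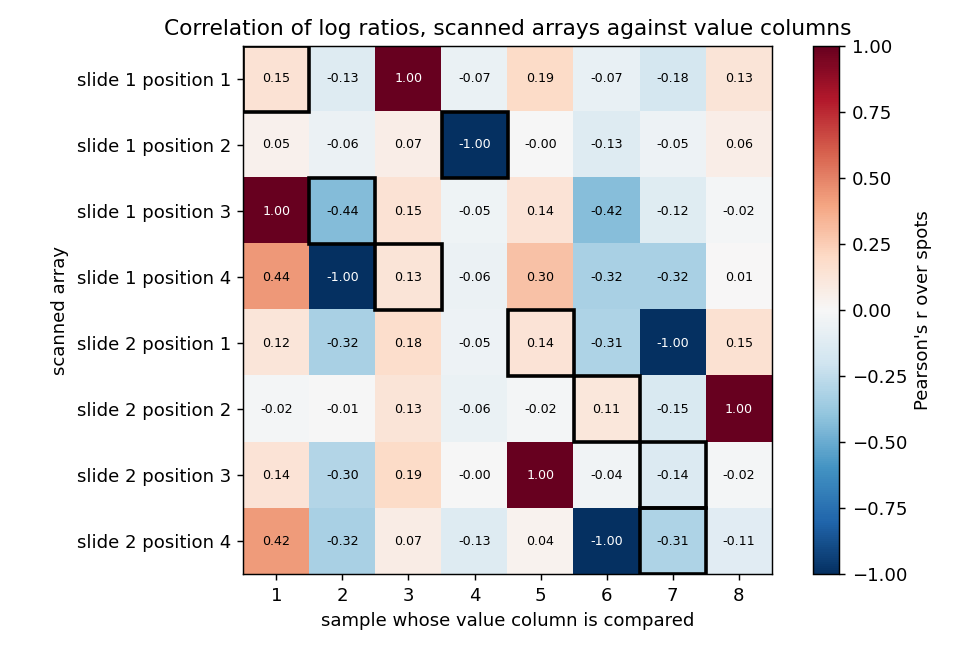
Correlation (Pearson's r, across spots) of log ratios between each scanned array (rows) and each sample's column of the deposited value table (columns), with the recorded sample boxed. Each row holds 1 value near 1 or -1, and the box lies on it in 1 row only; spots are not independent replicates.

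The share of probe spots well above background ran from 69.0% to 80.6% in Cy5 and from 65.5% to 76.9% in Cy3, over 43803 spots per array, and 0 spots were saturated. The number of arrays limits the precision: the median standard error of a probe was 0.06 log2 units for the mean of both slides and 0.13 for the difference between slides. Of 43603 distinct probes, 33724 were bright enough to test.

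The first comparison asked which spleen transcripts differed between infected and control hens over both slides. The list calls here came from a test with a preset correlation, and 0 lists passed with an estimated correlation (smallest adjusted p = 0.385 with an estimated correlation). By the preset test, genes normally expressed by the liver, such as the yolk proteins and fibrinogen, were lower in infected spleens as a group, most strongly on 2 of the 8 arrays. Antimicrobial peptide genes, heterophil genes (heterophils are the avian counterpart of neutrophils), macrophage genes and B cell genes were lower as groups. T cell, cytotoxic cell and cell cycle genes were slightly higher as groups. Cytokine and interferon genes did not differ as groups, and 0 single probes passed the threshold by limma, the smallest adjusted p being 0.502. At an unadjusted p under 0.05 there were 826 probes, 369 higher and 457 lower, against 1686 that chance alone would give. That count was 486 without replicate 5, 1448 without replicate 8, 1635 with array weights and 2033 on replicates 1 to 6.

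By camera with a preset correlation, 11 of 26 gene lists passed, 4 higher and 7 lower. With an estimated correlation 0 lists passed and by fry 0 passed, with smallest adjusted p of 0.385 and 0.551, against 11 at an unadjusted p under 0.05 with the preset, 1 with the estimate and 0 by fry. On replicates 1 to 6 alone 7 lists passed, 5 of them among these 11. With the direction of replicates 7 and 8 turned, 9 passed, 6 of them among these 11. The arrays filed as recorded, without replicate 6 and with replicates 1 and 2 turned, gave 8 lists, 4 of them among these 11. Leaving out replicate 1, 2 or 8 gave 6, 7 and 6 lists.

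The liver list fell (median log2 change -0.55 over 10 measured genes; per-array mean -0.56 ± 0.84, SD, n = 8; adjusted p = 7.32e-06). Its adjusted p = 0.385 with an estimated correlation. Of the 10 genes 9 were negative, 5 were lower at an unadjusted p under 0.05, and 0 passed either over all probes or adjusted over the list alone. The yolk precursors VTG2 (-1.18, SE 0.49) and VTG1 (-0.91, SE 0.39), fibrinogen beta chain FGB (-0.57, SE 0.23) and the thyroid hormone carrier TTR (-0.36, SE 0.15) had the smallest p. The first 3 were each lower on 5 of 6 arrays. Second probes of VTG2, VTG1, FGB and TTR stood at -0.31, -0.66, -0.49 and -0.43. TTR was dim, well above background in 2 of 8 infected and 6 of 8 control spleens. The list median was -2.38 in replicate 5 and -1.13 in replicate 3, and between -0.53 and 0.15 in the other arrays. In these 2 arrays the serum protein gene ALB stood at -4.53 and -3.87, and the egg-yolk apolipoprotein gene APOV1 at -4.94 and -4.82. Without replicate 5 the list median was -0.29, and without replicates 3 and 5 together it was -0.15 (adjusted p = 0.0168). It was -0.42 within slide 1, -0.80 within slide 2 and -0.87 on replicates 1 to 6.

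**Figure D2:**
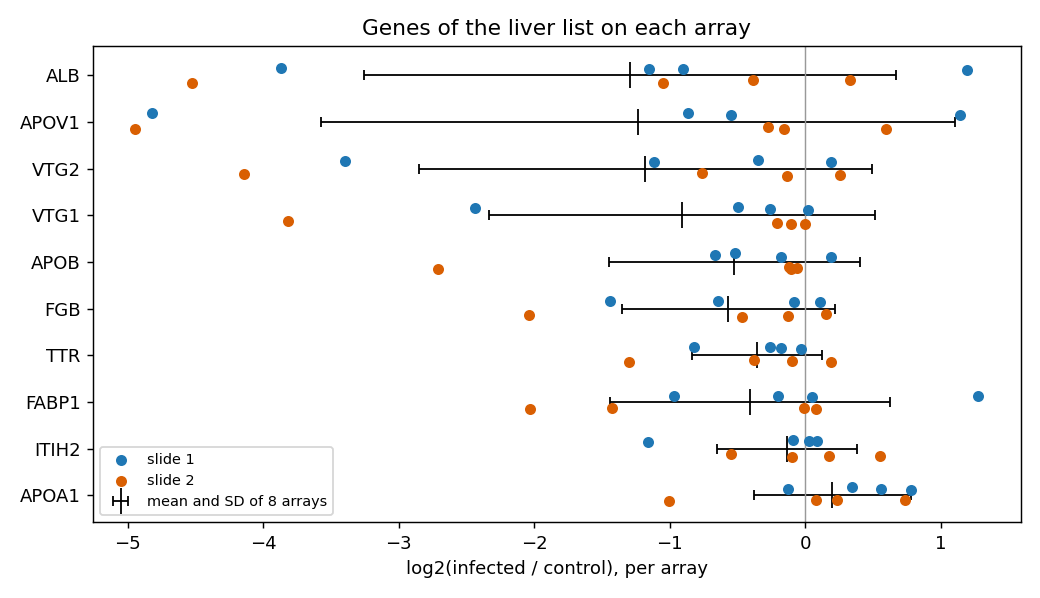
Log2 infected over control on each array for the 10 measured genes of the liver list, by slide, with the mean and SD of 8 arrays (black). ALB, APOV1, VTG2 and VTG1 lie far below 0 on 1 array of each slide, replicate 3 (ALB at -3.87) and replicate 5 (ALB at -4.53). By the deposited column's sign, replicates 7 and 8 would lie on the other side of 0.

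The antimicrobial list fell (median -0.32, 17 genes, per-array mean -0.21 ± 0.48, SD, n = 8; adjusted p = 0.0015; adjusted p = 0.385 with an estimated correlation), with 15 of 17 genes negative. The heterophil list, which shares 5 genes with it, fell as well (median -0.35, 11 genes, per-array mean -0.12 ± 0.54, SD, n = 8; adjusted p = 0.0284; adjusted p = 0.533 with an estimated correlation), with 9 of 11 negative. Over all probes 0 of their genes passed; adjusted over the list alone 2 antimicrobial genes and 1 heterophil gene did. The ribonuclease gene RNASE6 stood at -0.47 (SE 0.08, lower on 5 of 6 arrays), lysozyme LYZ at -0.26 (SE 0.07, 6 of 6), the beta-defensin AvBD9 at -1.10 (SE 0.44, 5 of 6) and AvBD10 at -0.15 (SE 0.08, 4 of 6), or -0.22, -0.19, -0.99 and -0.14 with replicates 7 and 8 turned. AvBD9 was lowest where the liver genes were, at -3.72 in replicate 5 and -3.42 in replicate 3. The defensin AvBD1, made by heterophils, ran from -2.66 in replicate 5 to 1.93 in replicate 4 among replicates 1 to 6. Among other heterophil genes ALAS1 stood at -0.07 and PADI3 at -0.12. The gelatinase MMP9 stood at 0.36 (SE 0.40), but at -0.15 on replicates 1 to 6 and at -0.61 with replicates 7 and 8 turned. Within slides 1 and 2 the antimicrobial medians were -0.18 and -0.18, and the heterophil medians -0.18 and -0.25. The antimicrobial call was lost without replicate 6 (-0.13), and its median was -0.175 without replicate 1 and -0.09 without replicate 5. The heterophil call was lost without replicate 1 (-0.14), 2 (-0.33), 5 (-0.07) or 6 (-0.13). On replicates 1 to 6 the medians were -0.60 and -0.42. With the arrays filed as recorded they turned to 0.15 and 0.18, and neither passed.

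The macrophage and monocyte list fell (median -0.09, 10 of 10 genes negative, per-array mean -0.08 ± 0.20, SD, n = 8; adjusted p = 0.00826; adjusted p = 0.465 with an estimated correlation), with 0 genes passing alone. Among the members with the smallest p were the lysosomal proteases CTSB (-0.23, SE 0.09) and CTSD (-0.22, SE 0.10) and the phagocytic receptor TIMD4 (-0.25, SE 0.17). The medians were -0.18 within slide 1 and 0.03 within slide 2. The call was lost without replicate 1 (-0.03) or 8 (-0.06) and on replicates 1 to 6 (-0.06, adjusted p = 0.152). With the arrays filed as recorded it turned to 0.08 and did not pass. The median was -0.18 without replicate 2 and -0.14 without replicate 3.

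The T cell list rose (median 0.10, 13 of 16 genes positive, per-array mean 0.10 ± 0.19, SD, n = 8; adjusted p = 4.36e-05; adjusted p = 0.385 with an estimated correlation). The co-receptor CD8A (0.24, SE 0.10), the cytokine receptor IL7R (0.18, SE 0.06), the co-stimulator CD28 (0.22, SE 0.10) and the receptor subunit CD3D (0.16, SE 0.09) had the smallest p, and 0 of the genes passed alone. These 4 stood, when replicates 7 and 8 were turned, at 0.13, 0.03, 0.14 and 0.14. A second probe stood at 0.03 for IL7R, 0.07 for CD28 and 0.18 for CD3D, and the 3 of CD8A ran from 0.18 to 0.27. CD3D and CD8A were above 0 on every array with the infected RNA in Cy5, and below 0 on those with it in Cy3 except replicate 6. IL7R and CD28 did not follow the dye in this way. CD3E stood at 0.18 (SE 0.11) and CD4 at -0.08 (SE 0.13). The medians were 0.01 within slide 1 and 0.22 within slide 2, 0.07 without replicate 6, 0.18 without replicate 8 and 0.22 on replicates 1 to 6. The cytotoxic and NK cell list rose (median 0.06, 5 of 6 genes positive, per-array mean 0.06 ± 0.19, SD, n = 8; adjusted p = 0.0358; adjusted p = 0.385 with an estimated correlation). In it GNLY stood at 0.12, FASLG at 0.06, the granzyme GZMA at 0.22 (SE 0.20) and TNFSF10 at 0.05, or -0.02 on replicates 1 to 6 and -0.05 with replicates 7 and 8 turned. GNLY and FASLG were above 0 on every array with the infected RNA in Cy5 and below 0 on every one with it in Cy3. The list's medians were 0.04 within slide 1 and 0.07 within slide 2. Its call was lost without replicate 2 (0.06), 3 (0.04), 4 (0.07), 5 (0.05) or 8 (0.06), and on replicates 1 to 6 (0.13, adjusted p = 0.0874), with replicates 7 and 8 turned (0.01) and with the arrays filed as recorded (0.03); the median was 0.11 without replicate 1 and 0.097 without replicate 7.

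The B cell list fell (median -0.13, 10 of 12 genes negative, per-array mean -0.13 ± 0.19, SD, n = 8; adjusted p = 0.00134; adjusted p = 0.385 with an estimated correlation). The kinase BTK (-0.15, SE 0.07), the transcription factor EBF1 (-0.16, SE 0.07), the surface protein CD72 (-0.29, SE 0.14) and the survival factor TNFSF13B (-0.23, SE 0.11) had the smallest p, and 0 genes passed alone. Turning replicates 7 and 8 gave -0.14, -0.06, -0.10 and -0.20 for these 4. Second probes of BTK, EBF1 and CD72 stood at -0.04, -0.04 and -0.02, and the 5 probes of TNFSF13B ran from -0.26 to 0.02. The chicken B cell marker Bu-1, named LOC396098 in the gene table, stood at -0.11 (SE 0.08). The medians were -0.07 within slide 1 and -0.16 within slide 2. The call was lost without replicate 2 (-0.10) and with the arrays filed as recorded (-0.05), the median was -0.06 without replicate 5, and it was -0.16 on replicates 1 to 6. The plasma cell list did not pass (median 0.01, 15 genes, adjusted p = 0.605), nor did its immunoglobulin joining chain gene JCHAIN (0.05, SE 0.29, and -0.40 on replicates 1 to 6 or -0.58 with replicates 7 and 8 turned).

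The cell cycle list rose (median 0.07, 25 of 30 genes positive, per-array mean 0.06 ± 0.36, SD, n = 8; adjusted p = 0.00022; adjusted p = 0.724 with an estimated correlation). The kinetochore gene NUF2 stood at 0.22 (SE 0.11), cyclin CCNA2 at 0.18 (SE 0.11; 0.01 with replicates 7 and 8 turned), CKAP2 at 0.14 (-0.0035 with replicates 7 and 8 turned) and the condensin subunit SMC2 at 0.13 (0.04 when turned). Second probes of NUF2 and CKAP2 stood at 0.10 and -0.01. The list's medians were 0.21 within slide 1 and -0.06 within slide 2. Replicate 6 lay far below the others, at -0.74; without it the median was 0.15, and it was 0.12 without replicate 2. The call was lost without replicate 4 (0.01) or 8 (-0.0014), and the median turned to -0.01 on replicates 1 to 6 and to -0.0028 with replicates 7 and 8 turned, neither past the test.

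The heat shock list fell (median -0.05, 12 of 16 genes negative, per-array mean -0.06 ± 0.13, SD, n = 8; adjusted p = 0.0284; adjusted p = 0.385 with an estimated correlation). The chaperones HSPA8 (-0.22, SE 0.07), HSPB1 (-0.13, SE 0.05), the collagen chaperone SERPINH1 (-0.19, SE 0.09) and FKBP4 (-0.07) had the smallest p, but stood at -0.0072, -0.11, -0.03 and -0.02 with replicates 7 and 8 turned. The 3 probes of HSPA8 ran from -0.22 to 0.07, the 3 of SERPINH1 from -0.19 to -0.05 and the 4 of FKBP4 from -0.10 to 0.06. A second HSPB1 probe stood at -0.13. The list's medians were -0.01 within slide 1 and -0.10 within slide 2. Its call was lost without replicate 1 (-0.04), 3 (-0.06), 4 (-0.06), 6 (-0.04), 7 (-0.05) or 8 (-0.04) and on replicates 1 to 6 (-0.05). With replicates 7 and 8 turned the median was 0.03 and did not pass. The circadian clock list fell (median -0.02, mean -0.08, 6 of 10 genes negative, per-array mean -0.06 ± 0.09, SD, n = 8; adjusted p = 0.0124; adjusted p = 0.385 with an estimated correlation). The period gene PER2 stood at -0.37, the nuclear receptor NR1D2 at -0.18 (SE 0.07), TEF at -0.24 (SE 0.09) and HLF at -0.10, or -0.07, -0.12 and 0.12 for the last 3 with replicates 7 and 8 turned; adjusted over the list alone 1 gene passed. Its medians were -0.04 within slide 1 and 0.02 within slide 2, where its mean was -0.10. Its call was lost without replicate 1 (0.01), 4 (-0.03) or 8 (-0.03), on replicates 1 to 6 (-0.03), with replicates 7 and 8 turned (-0.03) and with the arrays filed as recorded (-0.0064), and the median was -0.06 without replicate 2, -0.03 without replicate 3, -0.03 without replicate 7 and -0.008 without replicate 5. The ribosomal protein list rose (median 0.03, 20 of 28 genes positive, per-array mean 0.03 ± 0.24, SD, n = 8; adjusted p = 0.0198; adjusted p = 0.782 with an estimated correlation). In it RPL22 stood at 0.12, RPS15 at 0.11, RPL29 at 0.15 and RPS13 at 0.23. RPS13 was higher on only 3 of 8 arrays, at 2.09 in replicate 6 and 1.13 in replicate 8, and stood at -0.10 with replicates 7 and 8 turned. A second RPS13 probe stood at 0.0060. The list's medians were 0.04 within slide 1 and 0.02 within slide 2. On single arrays the list median followed the dye. It was above 0 wherever the infected RNA was in Cy5 (0.07 to 0.43). With that RNA in Cy3 it was below 0 on every array (-0.29 to -0.01). Its call was lost without replicate 1 (-0.0027), 2 (-0.0068), 6 (0.0064) or 7 (0.03), on replicates 1 to 6 (0.03) and with replicates 7 and 8 turned (0.02). With the arrays filed as recorded the list passed downward (-0.09), and the median was 0.06 without replicate 3 and 0.09 without replicate 4.

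Other processing ended some of these calls. Array weights ended the heterophil (-0.21), macrophage (-0.02), heat shock (-0.03), circadian clock (-0.0060) and ribosomal protein (-0.0043) calls, and scale normalization ended the heterophil call (-0.24). Leaving out the dye term ended the cytotoxic (0.06) and heat shock (-0.05) calls. The value table's ratios ended the cytotoxic (0.09), heat shock (-0.05) and ribosomal (0.03) calls. Median centring ended the heat shock (-0.07) and ribosomal (0.0015) calls, and taking the mean of a gene's probes ended the heat shock call (-0.02). The liver median was -1.42 with the scanner software's processed signals, -0.95 with the value table's ratios and -0.36 without the filter on dim probes, which brought its genes to 15.

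**Figure D3:**
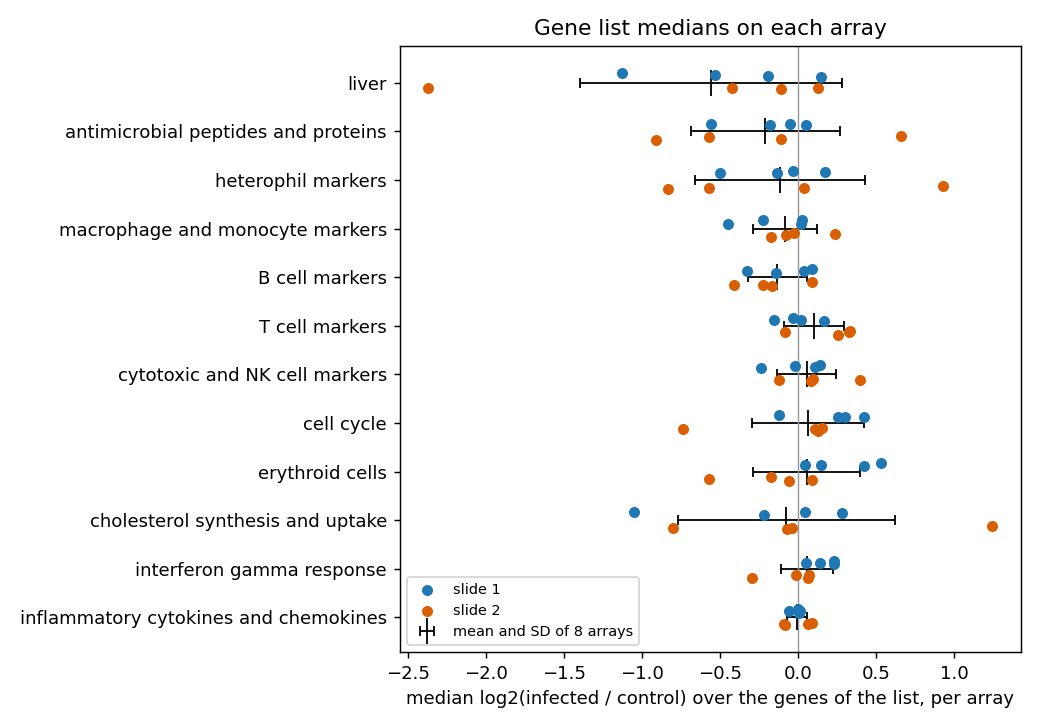
Median log2 infected over control of 12 gene lists on each of 8 arrays, by slide, with the mean and SD of the arrays (black). The liver list reaches -2.38 in replicate 5, the cell cycle list -0.74 and the cholesterol list 1.25 in replicate 6; the inflammatory list stays within 0.09 of 0 on every array. By the deposited column's sign, replicates 7 and 8 would lie on the other side of 0.

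The immune signalling lists did not pass. The inflammatory cytokine list had a median of -0.02 and a mean of 0.01 over 19 genes (adjusted p = 0.802). The interferon gamma list had a median of -0.01 and a mean of 0.03 over 15 genes, with the test pointing up (adjusted p = 0.358). The type I interferon list had a median of 0.0032 and a mean of -0.04 over 7 genes, with the test pointing down (adjusted p = 0.802). The pattern receptor list stood at -0.03 (11 genes, adjusted p = 0.447), the MHC and antigen presentation list at -0.03 (15 genes, adjusted p = 0.58) and the complement and acute phase list at -0.04 (7 genes, adjusted p = 0.286). Among single genes interferon gamma IFNG stood at 0.07 (SE 0.06), IL1B at 0.08 (SE 0.05), IL6 at -0.10 (SE 0.10), the chemokine IL8L2 at -0.04 (SE 0.07) and IL18 at -0.03 (SE 0.05). The nitric oxide synthase NOS2 stood at 0.08 (SE 0.07), the lipopolysaccharide receptor TLR4 at -0.22 (SE 0.11) and B2M at -0.01 (SE 0.06). On replicates 1 to 6 IL6 stood at 0.0042, and with replicates 7 and 8 turned IL1B stood at -0.04, IL6 at 0.12 and B2M at 0.10. IL10 and IL12B were too dim to test, and TLR15 was not analysed here. Adjusted over the list alone, 0 genes of these lists passed.

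The lists of other cell types and pathways that did not pass were thrombocytes (median 0.02), red cells (-0.02), cholesterol synthesis (-0.06), extracellular matrix (-0.05), endothelium (-0.01), pancreas (0.02), smooth muscle (-0.0028, mean 0.00091) and oxidative phosphorylation (-0.0052, mean 0.008). Their adjusted p ran from 0.356 for the pancreas list to 0.802 for the red cell list, and for the smooth muscle and oxidative phosphorylation lists the test pointed up. Adjusted over the list alone, 0 of their genes passed.

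None of the 24 single genes with the smallest p passed the threshold, and most were lower in infected spleens. PER2 came first (-0.37, SE 0.05, adjusted p = 0.547), with -0.36 and -0.38 within slides 1 and 2; a second PER2 probe stood at -0.05. PER2 was lower on 6 of 6 in replicates 1 to 6 (-0.34). With replicates 7 and 8 turned it was lower on 6 of 8, at -0.15 for the mean of both slides and 0.05 within slide 2. THRSP, a regulator of fat synthesis, stood at -0.62 (SE 0.14), PLCXD1 at -0.42 (SE 0.11), the muscle actinin ACTN2 at -0.32 (SE 0.07; dim, well above background in 1 of 8 infected and 6 of 8 control spleens) and the lysosomal enzyme IDUA at -0.15 (SE 0.04). Each was lower on 6 of 6 in replicates 1 to 6, at -0.78, -0.56, -0.25 and -0.17, and on 6 of 8 with replicates 7 and 8 turned, at -0.54, -0.29, -0.07 and -0.09. The butyrophilin-like MHC region genes BG8 (0.34, SE 0.08) and BG1 (0.32, SE 0.08) were higher on 6 of 6 in replicates 1 to 6 (0.36 and 0.26) and on 6 of 8 with replicates 7 and 8 turned (0.23 and 0.15); the 6 probes of BG8 ran from 0.31 to 0.66 and the 4 of BG1 from -0.14 to 0.32. The glucocorticoid receptor NR3C1 stood at -0.20 (SE 0.05), the fat hormone gene ADIPOQ at -0.29 (SE 0.06), the matrix protease MMP7 at -0.57 (SE 0.11), RSFR at -0.21, the fatty acid transporter CD36 at -0.22, MMACHC at -0.19 and C14orf180 at -0.28. With replicates 7 and 8 turned NR3C1 stood at -0.04, ADIPOQ at -0.16, MMP7 at -0.07, RSFR at -0.23, CD36 at -0.01, MMACHC at -0.21 and C14orf180 at -0.12. Others were SHISA2 (-0.47), NPL (-0.37), VPS45 (-0.29), CACNA2D1 (-0.19) and EHD3 (0.28), or -0.35, -0.07, -0.13, -0.08 and 0.33 when turned. CACNA2D1 was below 0 on every array with the infected RNA in Cy5 and above 0 on every one with it in Cy3. The highest other probe stood at 0.04 for SHISA2, 0.04 for VPS45, 0.0042 for NR3C1, 0.03 for MMACHC and 0.03 for IDUA. For SUCLG2 (-0.52, or -0.07 when turned) another probe of the gene stood at 1.08. For the Toll pathway inhibitor TOLLIP (0.60) another stood at 0.00010, and its value was 1.34 within slide 1 and -0.14 within slide 2.

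The next comparison asked what differed within slide 1, replicates 1 to 4. Red cell genes rose as a group (median 0.34, 11 of 13 genes positive; adjusted p = 1.31e-09), and this call held with an estimated correlation (adjusted p = 0.0486) but not by fry (adjusted p = 0.0647). RHAG, a red cell membrane protein, stood at 0.59 and the haemoglobin gene HBA1 at 0.44. Cell cycle genes rose (median 0.21, 29 of 30 positive; adjusted p = 0.536 with an estimated correlation) and macrophage genes fell (-0.18, 10 of 10 negative; adjusted p = 0.536 with an estimated correlation). Also past the preset test were thrombocyte (0.15) and interferon gamma (0.13) genes upward, each with adjusted p = 0.536 with an estimated correlation. Cholesterol (-0.25; adjusted p = 0.749 with an estimated correlation), liver (-0.42; adjusted p = 0.639 with an estimated correlation) and antimicrobial genes (-0.18; adjusted p = 0.592 with an estimated correlation) passed downward. That made 8 lists by camera, 1 of them with an estimated correlation and 0 by fry. Over all probes 0 passed by limma (smallest adjusted p = 0.352), with 796 at an unadjusted p under 0.05. That count was 1646 with array weights, 541 without the dye term and 427 with median centring. Adjusted over the list alone 2 red cell genes, 1 macrophage gene and 1 antimicrobial gene passed, and 0 in the other 5 lists.

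Several of the slide 1 calls rested on single arrays. Without replicate 1 the macrophage (-0.05), interferon gamma (0.08), cholesterol (-0.02) and antimicrobial (0.08) calls were lost, and the liver median was -0.66. Without replicate 2 the thrombocyte (0.085), cholesterol (-0.16), antimicrobial (-0.01) and liver (-0.50) calls were lost, and the macrophage median was -0.30. Without replicate 3 the thrombocyte (0.07), antimicrobial (-0.12) and liver (-0.32) calls were lost, and the medians were 0.21 for interferon gamma, -0.52 for cholesterol and -0.28 for macrophages. Without replicate 4 the thrombocyte (0.205), interferon gamma (0.02) and liver (-0.40) calls were lost, and the medians were 0.08 for the cell cycle and -0.51 for antimicrobial genes. Filed as recorded, the arrays ended the red cell (-0.03), macrophage (0.14), thrombocyte (0.03), interferon gamma (0.06) and antimicrobial (-0.0098) calls, and the cholesterol list passed upward (0.41). Array weights ended the interferon gamma (0.07), antimicrobial (-0.06) and cholesterol (-0.05) calls, and scale normalization the last 2 (-0.04 and -0.18). The interferon gamma call was also lost with processed signals (0.14), the antimicrobial call with median centring (-0.23), and both without the filter on dim probes (0.08 and -0.15). The liver median was -1.19 with processed signals. The thrombocyte median was 0.06 with array weights, 0.24 with processed signals and 0.23 with the value table's ratios.

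Within slide 2, replicates 5 to 8, red cell genes stood on the other side of 0 as a group. On these arrays in turn the list median was -0.06, -0.57, 0.09 and -0.17. The red cell list fell (median -0.12, 13 of 13 genes negative; adjusted p = 1.06e-07; adjusted p = 0.0741 with an estimated correlation), with RHAG at -0.53 and HBA1 at -0.58, or -0.07 and -0.08 with replicates 7 and 8 turned. T cell genes rose (median 0.22, 14 of 16 positive; adjusted p = 4.87e-06; adjusted p = 0.259 with an estimated correlation), CD8A at 0.52 and IL7R at 0.32, or 0.29 and 0.03 when turned. Liver (-0.80; adjusted p = 0.441 with an estimated correlation), B cell (-0.16; adjusted p = 0.441 with an estimated correlation) and heat shock genes (-0.10; adjusted p = 0.336 with an estimated correlation) fell. Extracellular matrix (-0.17; adjusted p = 0.522 with an estimated correlation), endothelium (-0.12; adjusted p = 0.388 with an estimated correlation) and antimicrobial genes (-0.18; adjusted p = 0.522 with an estimated correlation) fell too. That made 8 lists by camera, 0 with an estimated correlation and 0 by fry (smallest adjusted p = 0.0631). Over all probes 0 passed by limma, with 1250 at an unadjusted p under 0.05, a count that was 541 without replicate 5 and 2938 without replicate 8, on both sides of the 1686 that chance would give; adjusted over the list alone 5 red cell genes and 2 T cell genes passed, and 0 in the other 6 lists.

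This slide held both arrays of unsettled direction. With their direction turned, the red cell (-0.07, adjusted p = 0.405), B cell (-0.04), extracellular matrix (-0.05) and endothelium (-0.03) calls were lost, and the heat shock median was 0.04. With replicates 7 and 8 left out the liver median was -1.57, the antimicrobial median -0.83, the T cell median 0.44 and the red cell median -0.25, and the heat shock, extracellular matrix and endothelium calls were lost (-0.09, -0.20 and -0.17). Without replicate 5 the liver (-0.20), antimicrobial (-0.0074), B cell (-0.08), extracellular matrix (-0.09) and endothelium (-0.07) calls were lost, and the heat shock median was -0.15. Without replicate 6 the antimicrobial (-0.15) and extracellular matrix (-0.13) calls were lost, and the T cell median was 0.12. Without replicate 8 the antimicrobial (-0.46), B cell (-0.11), heat shock (-0.10), extracellular matrix (-0.08) and endothelium (-0.12) calls were lost, and the medians were 0.36 for T cells and -0.23 for red cells. Without replicate 7 the medians were -0.24 for red cells, -0.26 for B cells, -0.26 for extracellular matrix and -0.27 for antimicrobial genes. Arrays of slide 1 also entered through the shared spread and the choice of probes: the red cell median was -0.21 without replicate 3 and -0.21 without replicate 4, and the antimicrobial call was lost without replicate 2 (-0.18, adjusted p = 0.0583). Filed as recorded, the arrays ended the antimicrobial (-0.15) and extracellular matrix (-0.13) calls. Median centring ended the heat shock (-0.08), extracellular matrix (-0.12) and endothelium (-0.09) calls, the mean of a gene's probes the first 2 (-0.04 and -0.06), and array weights the heat shock call (-0.07). The antimicrobial call was lost with scale normalization (-0.22) and with the stricter filter on dim probes (-0.31). The liver median was -1.33 with processed signals and -0.39 without the filter. The red cell median was -0.24 with processed signals, -0.23 with separate fits per slide and -0.18 with array weights.

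The last comparison tested the difference itself, slide 2 minus slide 1, in the infected-to-control change; the labels do not say whether the slides also differ in day, birds or hybridisation. Red cell genes had the smallest adjusted p among the lists: all 13 were lower on slide 2 relative to slide 1 (median -0.36; adjusted p = 1.88e-12), and the call held with an estimated correlation (adjusted p = 0.0249) and by fry (adjusted p = 0.0101). Adjusted over the list alone 6 of them passed. RHAG differed by -1.12 (SE 0.14) and HBA1 by -1.02 (SE 0.16), or by -1.19 and -1.10 on replicates 1 to 6 and by -0.66 and -0.52 with replicates 7 and 8 turned. RHAG was above 0 on all 4 arrays of slide 1 and below 0 in replicates 5 and 6. The red cell median difference was -0.59 on replicates 1 to 6, -0.42 with replicates 7 and 8 turned, -0.21 without replicate 6 and -0.57 without replicate 8. With the arrays filed as recorded it was -0.13 and not past the test (adjusted p = 0.0845).

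**Figure D4:**
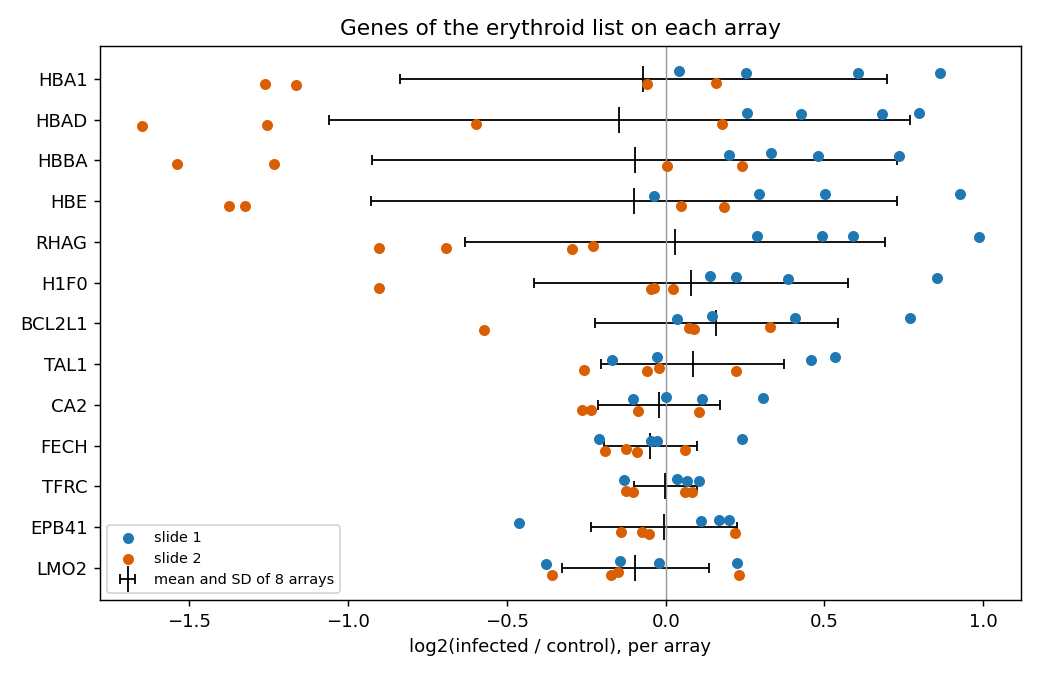
Log2 infected over control on each array for the 13 measured red cell genes, by slide, with the mean and SD of 8 arrays (black). RHAG and the haemoglobin genes HBA1, HBAD, HBBA and HBE differ most between slides on average, but HBA1, HBBA and HBE overlap between them. HBA1 lies at -1.26 in replicate 6 and -1.16 in replicate 8, against -0.06 in replicate 5 and 0.16 in replicate 7. By the deposited column's sign, replicates 7 and 8 would lie on the other side of 0.

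By camera 10 lists differed between slides, 3 upward and 7 downward, and only the red cell list with an estimated correlation and by fry. Cell cycle (-0.29), thrombocyte (-0.29), extracellular matrix (-0.14), interferon gamma (-0.15) and heat shock genes (-0.11) were lower on slide 2 relative to slide 1, and macrophage (0.23) and T cell genes (0.28) higher, each with adjusted p = 0.533 with an estimated correlation. Endothelium genes were lower (-0.13; adjusted p = 0.447 with an estimated correlation) and cholesterol genes higher (0.38; adjusted p = 0.859 with an estimated correlation). Over all probes 0 passed by limma (smallest adjusted p = 0.92), with 1093 at an unadjusted p under 0.05, or 659 without replicate 5 and 2550 without replicate 8, on both sides of the 1686 that chance would give. The genes with the smallest p after RHAG and HBA1 were the protein C receptor PROCR (0.80, SE 0.13), TMEM164 (0.68, SE 0.11), TOLLIP (-1.48, SE 0.26) and the splicing gene SNRPE (0.79, SE 0.15). With replicates 7 and 8 turned they stood at 0.33, 0.12, -1.42 and 0.06. Adjusted over the list alone 1 interferon gamma gene passed, and 0 genes of the other 8 lists.

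Most of these differences depended on single arrays. On replicates 1 to 6 the interferon gamma (-0.19), heat shock (-0.12) and endothelium (-0.22) calls were lost. With replicates 7 and 8 turned the T cell (0.23), interferon gamma (-0.23), extracellular matrix (-0.11) and endothelium (-0.10) calls were lost and the heat shock median was 0.04. Filed as recorded, the arrays kept only the extracellular matrix call (-0.20) in its direction, and the cholesterol list passed downward (-0.68). Without replicate 6 the T cell (0.14), thrombocyte (-0.19), cholesterol (0.05), interferon gamma (-0.09), extracellular matrix (-0.11) and heat shock (-0.12) calls were lost, and the cell cycle median was -0.10. Without replicate 1 the macrophage (0.10), cholesterol (0.08), interferon gamma (-0.05), heat shock (-0.16) and endothelium (-0.11) calls were lost, and the extracellular matrix median was -0.35. Without replicate 2 the thrombocyte (-0.11), cholesterol (0.27), extracellular matrix (-0.08) and heat shock (-0.07) calls were lost, and the medians were 0.185 for T cells and -0.23 for interferon gamma. Without replicate 3 the T cell (0.22), thrombocyte (-0.23), interferon gamma (-0.12), extracellular matrix (-0.06) and heat shock (-0.14) calls were lost, and the medians were 0.65 for cholesterol and -0.21 for endothelium. Without replicate 4 the interferon gamma (-0.02) and heat shock (-0.10) calls were lost. Without replicate 5 the extracellular matrix call was lost (-0.06), and the medians were 0.14 for macrophages and -0.09 for endothelium. Without replicate 7 the interferon gamma (-0.09) and heat shock (-0.14) calls were lost, and the medians were -0.32 for extracellular matrix and -0.21 for endothelium. Without replicate 8 the extracellular matrix (-0.06), heat shock (-0.09) and endothelium (-0.18) calls were lost, and the medians were -0.17 for thrombocytes and 0.76 for cholesterol. The interferon gamma and heat shock calls were each lost under 7 of the 10 processing alternatives. Array weights ended the macrophage (0.13) and cholesterol (0.04) calls, scale normalization the cholesterol call (0.22), median centring the extracellular matrix call (-0.03), and the mean of a gene's probes the T cell (0.08) and extracellular matrix (-0.08) calls.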

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

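The search for outlying arrays was planned and used a fixed rule on 26 lists and 82 genes, and no test of an explanation was run for what it found. A value was singled out where its gap to the nearest other array was too large a share of the range over 8 arrays by Dixon's test. Of 108 items, 7 (6.48%) had such an array; chance alone gives about 1 in 20. Signs follow the labelled dyes.

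Of these 7 values 5 were in replicate 6. The cell cycle list stood there at -0.74, the nearest other array being at -0.12, with its members SMC2 at -0.74 and CKAP2 at -0.71. The interferon gamma list stood there at -0.30, nearest other -0.01, and the gene IFNG at -0.36, nearest other 0.0058. In replicate 2 the smooth muscle list stood at 0.56, nearest other 0.08. In replicate 7, whose direction is unsettled, IL6 stood at -0.90, nearest other -0.11. No biological explanation was tested for these.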

How the results depend on the processing

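The leave-one-out, processing and list-test alternatives were planned; replicates 1 to 6 only, replicates 7 and 8 turned, the arrays as recorded, and leaving out replicates 3 and 5 together were chosen after the data were seen. In all 4 comparisons 0 probes passed by limma under every alternative run; with replicates 1 to 6 only there were 2033, 906, 3130 and 2655 probes at an unadjusted p under 0.05 (mean of both slides, slide 1, slide 2, difference). The count of 11 lists for the mean of both slides became 6 with array weights, 7 on replicates 1 to 6, 0 with an estimated correlation and 0 by fry, and 6 to 10 when leaving out 1 array; the other processing alternatives gave 8 to 11 and the other added ones 8 to 12. With an estimated correlation the loss follows from the wider null it uses; for the rest the cause was not tested.

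Where a list passed as reported or under the alternative, the direction of its test turned as follows, the cause not tested; lists that passed in neither turned too, in up to 8 of 25 alternatives (type I interferon). Mean of both slides: ribosomal list without replicate 1 (range over single arrays left out -0.0068 to 0.085); on replicates 1 to 6, plasma cell -0.13 and cell cycle -0.011; with 7 and 8 turned, plasma cell -0.086, red cell 0.067 and heat shock 0.031; as recorded, antimicrobial 0.15, heterophil 0.18, macrophage 0.079, MHC 0.12 and ribosomal -0.091. Slide 1 as recorded: antimicrobial -0.0098 (its test pointing up), macrophage 0.14, red cell -0.029 and cholesterol 0.41. Slide 2 with 7 and 8 turned: heat shock 0.037. Difference: cholesterol without replicate 6 (the test only; medians 0.051 to 0.76), heat shock 0.042 with 7 and 8 turned, and as recorded macrophage -0.14, cell cycle 0.0445 and cholesterol -0.68. Signal over background limited what was tested: IL10 and IL12B were too dim on most arrays.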

Other observations

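The tests of the red cell, liver and dye patterns were chosen only after the results were seen; the counts over other splits of the arrays were planned. Genes of cholesterol synthesis and uptake varied widely between arrays: the list median was 1.25 in replicate 6, -1.05 in replicate 1, -0.80 in replicate 8, whose direction is unsettled, and between -0.22 and 0.28 in the other arrays. Extracellular matrix genes from -0.44 in replicate 5 to 0.49 in replicate 2. Some heterophil granule genes differed in sign between replicates 4 and 5, where the deposited sign is that of the labelled dyes: AvBD7 stood at 1.69 and -2.88, CATH1 at 1.22 and -2.60, and CATH2 at 1.32 and -2.79. In the heterophil list AvBD1, LECT2, LYG2 and NCF4 went the same way. MMP9 (-1.65 and 0.47) and ALAS1 (-0.05 and 0.05) went the other way, and RNASE6, PADI3 and CSF3R were below 0 in both. AvBD7, CATH1 and CATH2 were picked after their values were seen.

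Red cell genes were lower on slide 2 relative to slide 1 in the infected-to-control change. The unsettled direction of replicates 7 and 8 does not account for all of it, since on replicates 1 to 6 the median difference was -0.59. Slide 2 then holds only replicates 5 and 6, with list medians of -0.06 and -0.57, so this value rests mainly on replicate 6. Blood left in the spleens, differing between infected and control birds from slide to slide, may account for the slide difference. Thrombocytes, which also come with blood, had a median difference of -0.29, a call lost with an estimated correlation (adjusted p = 0.533 with an estimated correlation). Both lists were lowest in replicate 6 (-0.38 for thrombocytes). The red cell list was highest in replicate 1 (0.53), where the thrombocyte list stood at 0.03. Cell cycle genes also differed between slides (-0.29), likewise not with an estimated correlation. The thrombocyte value therefore does not decide. Of the 34 splits of the 8 arrays into 4 and 4 that could be fitted, 4, the real one included, gave a red cell difference as large as the 0.36 seen, the highest other being 0.58, so chance is not excluded. A difference between the days of sampling, which the labels do not tie to slides, stays open and untested.

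Liver genes were lower in infected spleens mainly in replicates 3 and 5. Among replicates 1 to 6 the list median ran from -2.38 in replicate 5 to 0.15 in replicate 2. Each array sets 1 infected against 1 control spleen, so this spread may come from either. It does not decide whether infection acted alike on every spleen. A shared effect, of the same or of varying size, stays open. The list was below 0 on 6 of 8 arrays, a count that takes in the 2 of unsettled direction and decides nothing. The bound on this count was first written as 6 or fewer, which the count meets, and was moved to 4 or fewer after the count was seen. Without replicates 3 and 5 the list still passed (-0.15, adjusted p = 0.0168), a call from the preset correlation. Liver tissue taken along with the control spleens of replicates 3 and 5 is a candidate explanation, and 7 of the 10 liver genes were below -0.5 on both arrays, while APOA1, ITIH2 and FABP1 were not, so the values do not decide. FABP1, a gene the liver expresses strongly, stood at 1.28 in replicate 3, which counts against it there. The state of lay of these birds is an open biological alternative that no label gives.

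Arrays resembled each other by dye more than by infection. Over 16 pairs of arrays with opposite dyes the mean correlation across probes of Cy5 over Cy3 was 0.153, above 0 in 14 pairs, which a gene-specific dye effect may give. The labelled direction of replicates 7 and 8 is not decided by their likeness to the others: with dyes balanced, their mean correlation with replicates 1 to 6 was -0.0367, against 0.0033 within replicates 1 to 6. Probes are not independent replicates.

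Other splits of the 8 arrays do not exclude chance for the mean of both slides. For probes past the threshold the splits decide nothing: the real split had 0, so all 100 drawn had at least as many, the highest other having 485. Of the 100, 81, the real one included, had at least 826 probes at an unadjusted p under 0.05, the highest other having 8019. The high counts of some splits point to a structure of the samples, the dyes among the open sources, and what produced it was not tested. Of the 100 splits 7 had any probe past the threshold, and 0 of the 13 with dyes balanced on each slide did. For lists, 5 of 100 splits, the real one included, called at least the real 11, the highest other calling 11. Among the 13 with dyes balanced on each slide, the real one included, the highest other called 11 as well. For the slide difference 4 of 34 splits, the real one included, called at least the real 10 lists, the highest other calling 12, so chance is not excluded there either. Within a slide 8 splits are too few for a share under 0.05: slide 1 called 8 lists and the highest other 6 (1 split as large, the real one), and slide 2 called 8 and the highest other 12 (3 splits as large, the real one included).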
